A study of Mus musculus with 12 samples.

How the data were processed

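Gene expression was measured on 12 one-colour chemiluminescent arrays. Per the labels, total RNA was extracted with TRI-Reagent and Qiagen columns and turned into digoxigenin-labelled cRNA with an Applied Biosystems chemiluminescent labelling kit. The animals were male mice of the congenic strain B6.CAST-17, which carries a segment of chromosome 17 from the wild-derived strain CAST on the inbred background B6, and wild type B6 mice. The series text gives 3 mice per strain as biological replicates and names both tissues, which read literally means that each mouse gave both. Skeletal muscle and hypothalamus were profiled, which gave 4 groups of 3 arrays. Groups were taken from the sample titles. The description field names the congenic strain for every sample, wild type included, and was not used. Only the titles of the hypothalamus samples call the congenics short, however, and no sample label says that both tissues came from the same mice or congenic line, so there may have been 6 mice per strain. It is not stated that a number marks the same mouse in both tissues, so the tissues were not paired.

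The values deposited by the authors were taken as log2 intensities. No label names the base, which was inferred from the range of 5.35 to 21.1, so every fold given rests on base 2. All 33012 probes had a value on every array. The 6 arrays of a tissue shared 1 distribution, as quantile normalization within the tissue gives, with a median of 9.12 in muscle and 8.98 in hypothalamus. The software and the background correction are not given in the sources used here, and no detection calls were available, so signal over background is unknown and low values cannot be told from background. The number of arrays limits the precision. No 2 arrays held identical values. The values were used as deposited, with no floor and no filter.

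Probes were named from the platform annotation: 14411 carried 1 gene symbol, 247 carried several and 18354 had no gene name. Of the first kind 14402 matched a gene table of the mouse assembly GRCm38.p6, used only for names, chromosome membership and gene order. They covered 13840 genes, of which 13832 had a chromosome and 656 were on chromosome 17. For tests on genes, the probe with the highest mean over the 12 arrays stood for the gene. The platform's own build is not named, so the planned 10 Mb bins of chromosome 17 were replaced by 10 blocks of genes in chromosome order.

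Strain effects were tested in each tissue alone, as congenic minus wild type, with limma 3.58.1 in R 4.3.3 (lmFit, eBayes with a mean-variance trend) over all probes, with Benjamini-Hochberg adjustment and a threshold of 0.05. The difference between the tissues' strain effects was an interaction contrast over the 12 arrays. Two-sided Fisher's exact tests compared the share of genes with an unadjusted p under 0.01 on chromosome 17 with that on other chromosomes, and counted genes that moved the same way in both tissues. They take genes as independent units, so their p-values and intervals do not measure the spread between mice. Intervals of shares are Clopper-Pearson intervals at 95%. For 36 lists of pathway genes and cell type markers, 23 were run in muscle and 28 in hypothalamus where at least 5 genes were measured, with limma's camera at a preset correlation of 0.01, adjusted over the lists of a tissue. Camera with an estimated correlation and fry were alternatives. The groups, tests, lists, thresholds, naming rule and most alternatives were fixed before the data were examined. Leaving out each array in turn was planned. The fuller report without wild type hypothalamus array 1, which stood apart, was added afterwards. So was the fit that also left out congenic hypothalamus array 1, which held high pituitary hormone values.

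Genes named are, per tissue, those that passed with 1 gene symbol, at most 10 in each direction. Where fewer than 5 passed, those with the smallest p filled up to 5 and are given as values that did not pass. Up to 5 genes in each direction come from the interaction test and 2 to 4 from each list called, and probes without a gene name that passed are given by number. The naming rule was applied again without wild type hypothalamus array 1.

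The fits were tested on simulated data with 33012 probes and the design of each comparison. Noise was normal and independent between probes and arrays, with each probe's mean and residual SD, and no simulated array stood apart. In hypothalamus 5.07% of unchanged simulated probes had a limma p under 0.05, where the real data gave 658 of 33012 probes. The simulation thus does not reproduce that fit, and its counts are a rough guide. In muscle 2 of 67 probes changed 2-fold were recovered, 28 of 67 changed 4-fold and 56 of 66 changed 16-fold, with 1 false call. In hypothalamus the counts were 0 of 67, 1 of 67 and 11 of 66, and without wild type array 1 they were 0 of 67, 4 of 67 and 37 of 66. The interaction test recovered 86 of 200 probes changed 16-fold, with 4 false calls. Alternatives covered normalization, a filter on dim probes, a floor, the variance model, array weights, a joint fit, a replicate block, another test and leaving out each array in turn.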

Results

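Skeletal muscle and hypothalamus of male B6.CAST-17 congenic mice were compared with those of wild type B6 mice, with 3 arrays per strain and tissue. The series concerns a strain that differs from B6 in physical activity and carbohydrate preference. Markers of the tissues followed the titles. The median of 11 skeletal muscle genes was 19.88 to 20.12 (log2) on the muscle arrays and 8.66 to 9.20 on the hypothalamus arrays. The median of 9 neuronal genes was 15.74 to 16.99 on 5 hypothalamus arrays, 12.28 on wild type hypothalamus array 1 and 8.18 to 8.97 on the muscle arrays. Spearman correlations between arrays across probes were 0.796 to 0.862 in muscle. Wild type hypothalamus array 1 gave 0.420 to 0.461 with the other 5 arrays of its tissue, which gave 0.775 to 0.853 among themselves.

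In muscle 4 named genes passed the test of the strain difference, all of them on chromosome 17. H2-Ea, the alpha chain of the class II histocompatibility molecule I-E, rose to 12.61 ± 0.60 (SD, n = 3) in congenic muscle from 7.31 ± 0.11 (n = 3) in wild type muscle, a difference of 5.31 (SE 0.41), or 39.6-fold, with an adjusted p of 0.00194 (limma). Atp6v0e, a subunit of the vacuolar proton pump, rose to 16.41 ± 0.02 from 14.61 ± 0.31, a difference of 1.80 (SE 0.18; limma adjusted p = 0.0126). Taf11, a subunit of the general transcription factor TFIID, fell to 12.31 ± 0.55 from 15.01 ± 0.13, or 6.51-fold, and Pla2g7, which encodes platelet-activating factor acetylhydrolase, fell to 11.96 ± 0.25 from 14.21 ± 0.21, or 4.75-fold (limma adjusted p = 0.0124 for both). For each of these genes the 3 congenic arrays lay on one side of the 3 wild type arrays.

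The mean of H2-Ea in wild type muscle was at percentile 0.124 of all probes, so its fold depends on where background lies. Beside these genes, limma called 2 probes without a gene name, 858145 (-5.11, adjusted p = 0.000727) and 366579 (-2.68, adjusted p = 0.00194), which made 2 probes higher and 4 lower of 33012. Unadjusted p-values under 0.05 were found for 1653 probes, where 1650.6 would be met by chance. Among genes that did not pass, Ppp1r11, an inhibitor of protein phosphatase, differed by 1.35 (limma adjusted p = 0.298), and Rsph1, a radial spoke protein of cilia, by 1.77 (0.306). Dynlt1b, a dynein light chain, differed by 0.95 (limma adjusted p = 0.306). The differences of Ppp3cb, a catalytic subunit of calcineurin, of Rnaset2b and of Gnat1 were -1.24, -0.77 and -1.96, with limma adjusted p-values of 0.770, 0.835 and 0.835. The number of probes called was 3 without congenic array 2, 2 without wild type array 2 and 3 without wild type array 3. H2-Ea passed with each array left out, with limma adjusted p-values of 0.00151 to 0.0386, but not with values floored at the 20th percentile (4.59, limma adjusted p = 0.149). Atp6v0e did not pass without congenic array 1 or 2 or wild type array 2 or 3, Taf11 without congenic array 2 or any wild type array, Pla2g7 without congenic array 1 or 2 or any wild type array, and probe 366579 without wild type array 2, with limma adjusted p-values up to 0.177. In a fit of all 12 arrays, H2-Ea alone passed.

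**Figure D1:**
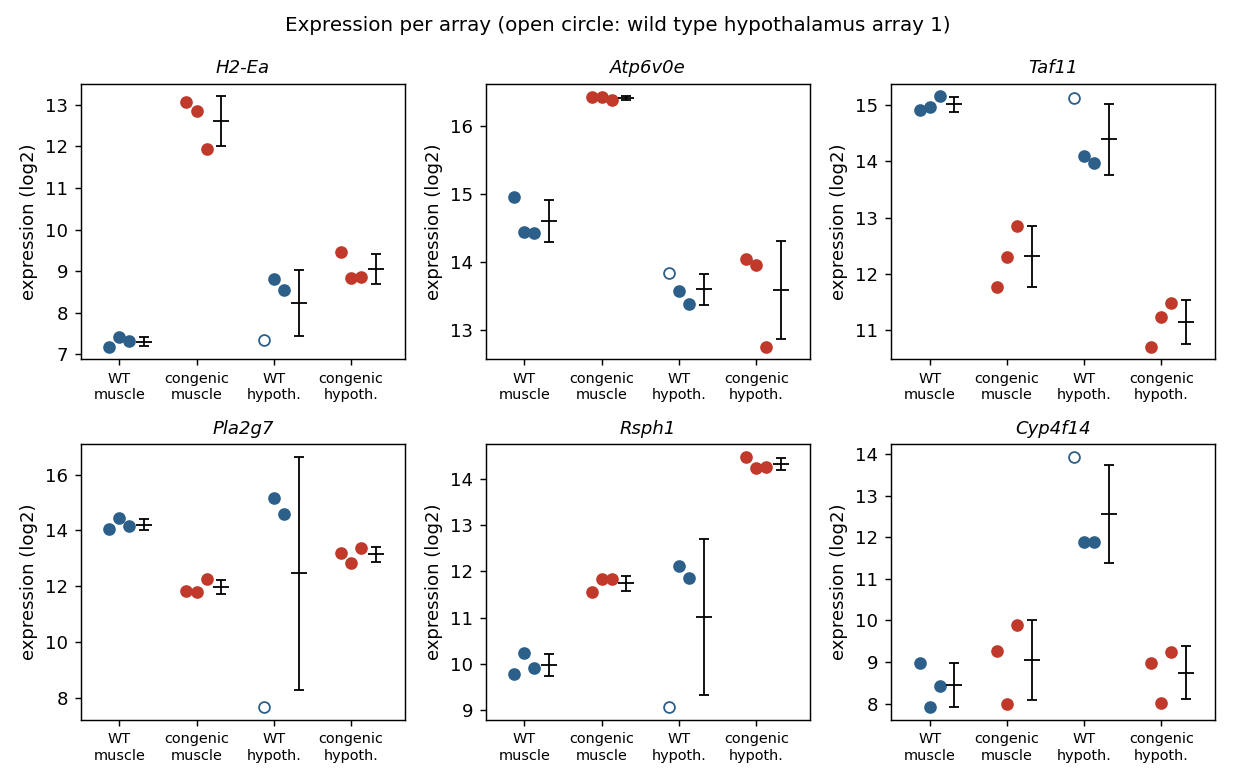
Expression (log2) of 6 chromosome 17 genes on each of the 12 arrays, with the mean and SD of each group of 3 beside the points. H2-Ea lay between 11.93 and 13.06 on the congenic muscle arrays and between 7.19 and 7.42 on the wild type muscle arrays; open circles mark wild type hypothalamus array 1.

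Of the 23 gene lists run in muscle, camera called 5. Regulators of mitochondrial biogenesis and of the response to exercise were lower in congenic muscle: 17 of 20 members had negative differences, with a median of -0.37 (camera in limma, adjusted p = 0.000168; adjusted p = 0.226 with an estimated correlation). The estimated correlation of this list was 0.0062, below the preset 0.01, so the larger p did not come from a larger correlation. Mef2c, a transcription factor of muscle, differed by -1.07, Nrf1, a transcription factor of nuclear genes for mitochondria, by -0.77, and Hk2, the hexokinase of muscle, and Nr4a3, a nuclear receptor, by -0.40 and -0.39. A second, dimmer probe of Nrf1 gave 1.41. Mef2c was 15.26, 15.32 and 13.18 on the congenic arrays, and without congenic array 3 the differences of Mef2c, Nrf1 and Hk2 were -0.37, -0.50 and -0.22. Genes of the tricarboxylic acid cycle were lower too, with 13 of 16 negative and a median of -0.19 (camera in limma, adjusted p = 0.0109; adjusted p = 0.530 with an estimated correlation). Their values included -0.93 for Sucla2, -0.61 for Dld, -0.43 for Sdha and -0.36 for Idh3a, and without congenic array 3 those of Sucla2, Dld and Idh3a were -0.21, -0.24 and -0.23. Idh3a differed by -0.24 without wild type array 2. In both lists 0 members passed limma over all probes or adjusted over the list alone.

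The other 3 lists called by camera in muscle were those of macrophages, histocompatibility genes and fibroblasts, and interferon-stimulated genes were not called (camera adjusted p = 0.224 in limma). Macrophage and microglia markers had 6 of 8 positive differences and a median of 0.35 (camera in limma, adjusted p = 0.00910; adjusted p = 0.530 with an estimated correlation). The 3 chains of complement component C1q differed by 0.99 (C1qa), 0.92 (C1qb) and 0.82 (C1qc), and these 3 markers passed when adjusted over the list alone and 0 passed over all probes. Mrc1, a mannose receptor of macrophages, differed by 0.40, by 0.71 without congenic array 3 and by 0.26 and 0.23 without congenic array 1 or 2. The median of the macrophage markers was 0.66 without congenic array 3, 0.21 without congenic array 2 and 0.23 without wild type array 2. Class I and II histocompatibility genes had 14 of 18 positive differences and a median of 0.27 (camera in limma, adjusted p = 0.0109; adjusted p = 0.530 with an estimated correlation). Of these, 1 gene (H2-Ea) passed over all probes and 7 adjusted over the list alone, of which H2-Aa and H2-Q10 were lower. The class I genes H2-Q7 and H2-Q2 differed by 0.68 and 1.15, the class I gene H2-Q10 by -2.49, and the class II gene H2-Aa by -0.92. Without H2-Ea the 17 other genes gave a camera adjusted p of 0.127 in limma, and without wild type array 1 the median of the list was 0.46. Fibroblast and tendon markers had 10 of 12 positive differences and a median of 0.28 (camera in limma, adjusted p = 0.0222; adjusted p = 0.540 with an estimated correlation). The collagens Col1a1, Col1a2 and Col3a1 differed by 0.76, 0.50 and 0.47 and the tendon transcription factor Scx by 0.57, and 0 members passed over all probes or adjusted over the list alone. Without congenic array 3 Col1a2 differed by 0.30 and Scx by 0.21. The median of the fibroblast and tendon markers was 0.50 without congenic array 1, 0.15 without wild type array 2 and 0.45 without wild type array 3.

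None of the 5 lists was called with an estimated correlation or by fry. The number of lists called was 3 without congenic array 1, 2 without congenic array 2, 1 without wild type array 2 and 3 without wild type array 3, and the mitochondrial regulators were called in each of these, with camera adjusted p-values up to 0.00380 in limma. The histocompatibility genes were not called without congenic array 1 or 2 or wild type array 2 or 3, macrophage markers without congenic array 1 or 2 or wild type array 2, tricarboxylic acid cycle genes without congenic array 2 or wild type array 2 or 3, and fibroblast markers without congenic array 2 or wild type array 2, with camera adjusted p-values up to 0.262 in limma. With all chromosome 17 genes left out, camera adjusted p-values in limma were 8.70e-05 for the mitochondrial regulators, 0.000661 for macrophage markers, 0.0124 for the tricarboxylic acid cycle and 0.0266 for fibroblast markers. The histocompatibility list was not run so, as most of its genes lie on chromosome 17 and fewer than 5 remained. Its call therefore cannot be told from an effect of the transferred segment. The other 18 lists gave camera adjusted p-values of 0.0792 to 0.900 in limma. They included blood (0.0792, 8 of 8 positive), oxidative phosphorylation (0.185), fast fibre genes (0.438), slow fibre genes (0.550) and glycolysis (0.900). For the circadian clock and adipocyte lists the median and the test differed in sign.

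**Figure D2:**
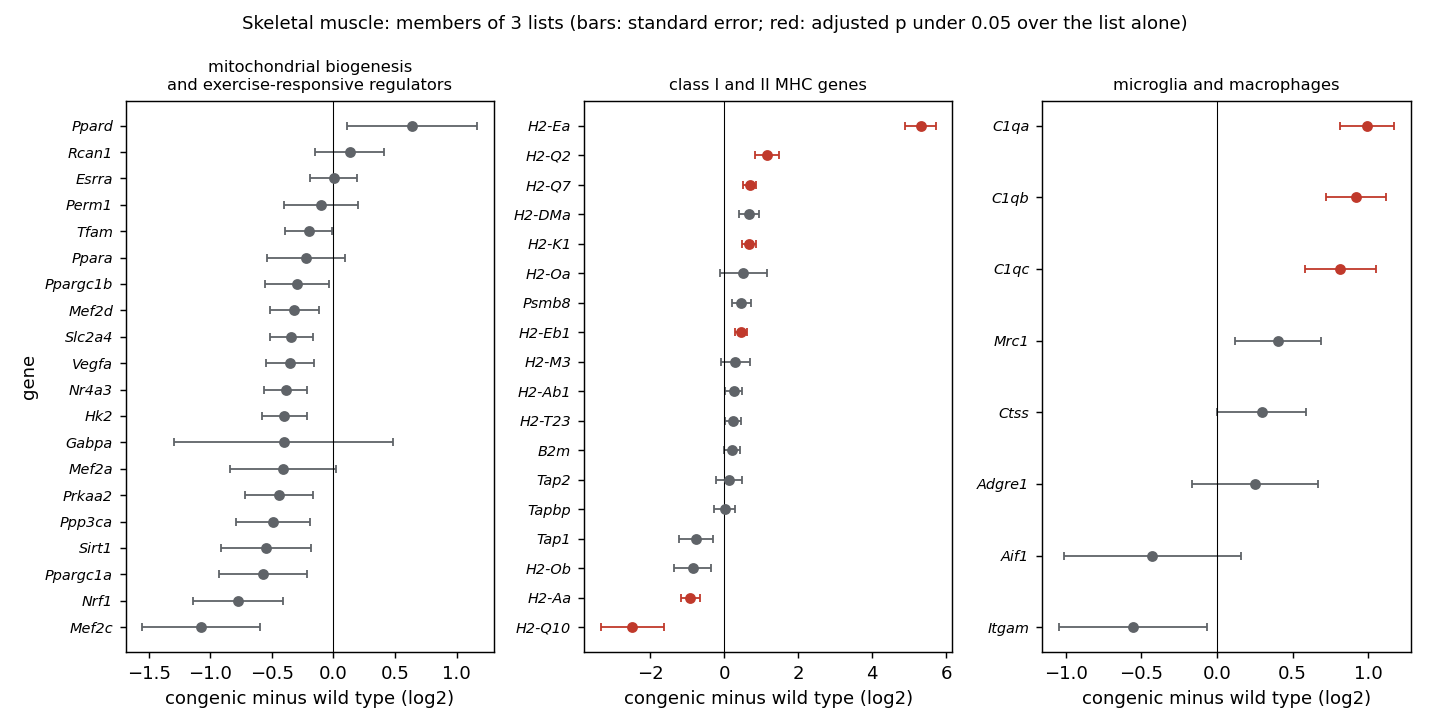
Differences (congenic minus wild type, log2) in muscle of the measured members of 3 of the lists called, with standard errors from limma; red marks members that passed adjusted over the list alone. The medians were -0.37 for the mitochondrial regulators and 0.35 for macrophage and microglia markers.

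The congenic segment lies on chromosome 17, and genes with a strain difference were more frequent there than elsewhere. In muscle 28 of 656 chromosome 17 genes (4.27%) had an unadjusted limma p under 0.01, against 82 of 13176 genes on other chromosomes (0.622%), an odds ratio of 7.12 (95% interval 4.43 to 11.1; Fisher's exact test, p = 1.34e-13). The odds ratio was 3.84 without congenic array 1 and 4.24 without wild type array 1 (exact p = 7.20e-08 and 8.44e-08). The next highest share was 1.03%, on chromosome 4. Of the 28 genes, 19 were higher and 9 lower in congenic muscle. At an adjusted p under 0.05 there were 4 genes on chromosome 17 and 0 elsewhere (Fisher's exact test, p = 5.02e-06). In chromosome order, 27 of the 28 were among the 458 genes of the first 7 blocks, which end with Rrp36, and 1 was among the 197 genes of the last 3. This division was chosen after the values were seen and was not tested. A comparison, also not planned, of the first 5 blocks (19 of 327 genes) with the last 5 (9 of 328) gave an odds ratio of 2.18 (Fisher's exact test, p = 0.0558).

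In hypothalamus 4 of 656 chromosome 17 genes (0.610%) and 13 of 13176 others (0.0987%) had an unadjusted limma p under 0.01, an odds ratio of 6.21 (1.47 to 20.2; Fisher's exact test, p = 0.00728), with 1 gene higher and 3 lower. A split of the arrays that mixed the strains gave an odds ratio of 5.04, so this p-value is weak evidence for a strain effect. Without wild type array 1 the counts were 28 and 135, and the odds ratio was 4.31 (2.74 to 6.57; Fisher's exact test, p = 2.75e-09), with 11 genes higher and 17 lower. Of these 28 genes 24 were in the first 7 blocks and 4 in the last 3. With all other arrays kept, the odds ratio was 2.16 (exact p = 0.180) without congenic array 1, 4.03 (exact p = 0.108) without congenic array 2, 3.02 (exact p = 0.0931) without congenic array 3 and 2.78 (exact p = 0.0691) without wild type array 3.

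**Figure D3:**
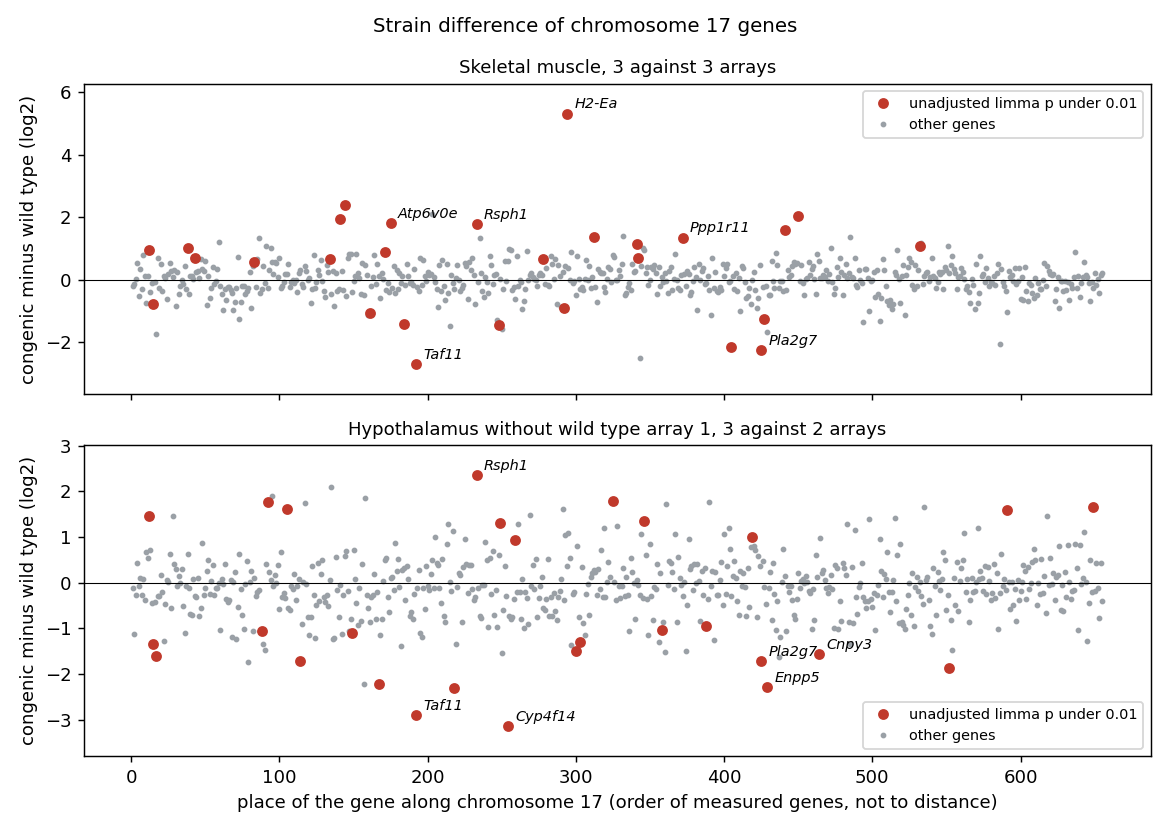
Strain difference (congenic minus wild type, log2) of measured chromosome 17 genes in chromosome order, in muscle and in hypothalamus without wild type array 1. Larger red points mark genes with an unadjusted limma p under 0.01, 28 in each panel; the horizontal axis gives order and not distance.

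In hypothalamus no gene passed the test, and the differences with the smallest p-values were again partly on chromosome 17. Over all 6 arrays, Taf11 was 11.14 ± 0.40 (SD, n = 3) in congenic and 14.40 ± 0.63 (n = 3) in wild type mice, and Rsph1 14.33 ± 0.13 against 11.01 ± 1.69. Cyp4f14, a cytochrome P450 gene on chromosome 17, was 8.75 ± 0.64 against 12.57 ± 1.18. The other values with small p were 1.70 for Cenpi, 1.46 for Trim30d, 2.01 for Gzf1 and 2.26 for Clcc1, and -2.69 for Sh3bp2, -2.37 for Pcdha4 and -1.38 for Sgca, each with a limma adjusted p of 0.936. By limma 0 of 33012 probes were called, and 658 had an unadjusted p under 0.05, where chance gives 1650.6. An equal-variance test of each probe also called 0.

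Wild type hypothalamus array 1 stood apart, and the median residual SD of the probes was 0.782 with it and 0.494 without it. Of 4165 probes with a mean above 13 on the other 5 arrays, 1393 (33.4%) were more than 3 log2 units lower on this array. Each of those 5 arrays, compared in the same way with the rest of the 5, gave 0% to 0.119%. Without it limma again called 0 probes, 1761 had an unadjusted p under 0.05, and the smallest adjusted p was 0.310. In this comparison of 3 arrays with 2, Slc6a3, the dopamine transporter, was 10.20 ± 0.69 in congenic and 13.57 ± 0.23 in wild type hypothalamus, a difference of -3.37 (limma adjusted p = 0.383). Over all 6 arrays Slc6a3 differed by -1.29, and by -0.34 and -0.17 when wild type array 2 or 3 was left out in place of array 1. Taf11 differed by -2.90 and Rsph1 by 2.35 (limma adjusted p = 0.310 for both), and Enpp5, an ectonucleotide pyrophosphatase family member, by -2.28 (0.383). Stk32c, Olfr298, Tmed9 and Tubb2b differed by 2.35, 2.62, 1.85 and 2.45, and Cyp4f14 and Pla2g7 by -3.14 and -1.73, with limma adjusted p-values of 0.731, 0.764, 0.900, 0.900, 0.764 and 0.900. Over all 6 arrays Enpp5 differed by -1.17, Stk32c by 0.66, Tmed9 by 0.76, Tubb2b by 1.49 and Pla2g7 by 0.68. With wild type array 2 or 3 left out in place of array 1, Enpp5 gave -0.64 and -0.59 and Tmed9 0.14 and 0.28. Tubb2b gave 0.91 without wild type array 3.

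**Figure D4:**
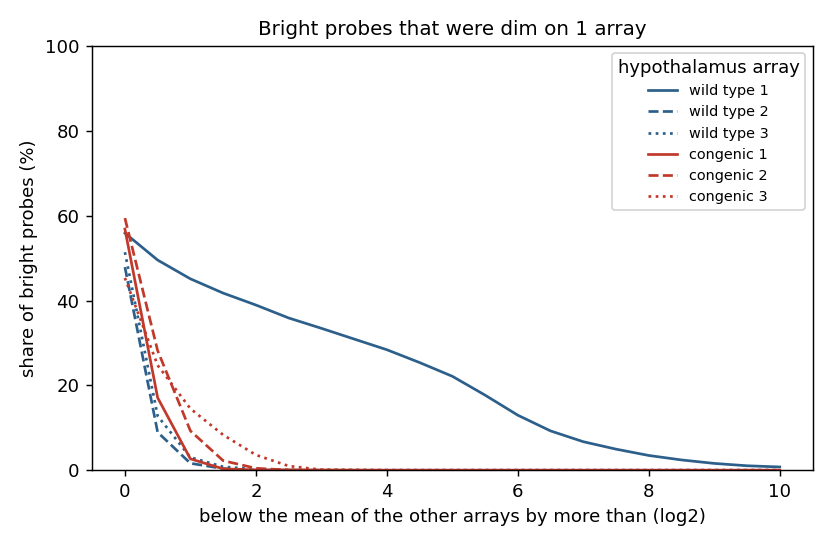
Share (%) of bright probes that lay below the mean of other hypothalamus arrays by more than a given amount (log2), for each of the 6 arrays. Wild type array 1 was compared with the other 5 arrays, and it was left out of the mean for each of those 5. At 3 log2 units the share was 33.4% on wild type array 1 and at most 0.119% on the others.

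Of the 28 lists in hypothalamus, camera called 1 over all arrays. Oligodendrocyte markers were higher in congenic mice, with 6 of 6 positive and a median of 1.22 (camera in limma, adjusted p = 0.0176; adjusted p = 0.662 with an estimated correlation). Mbp, myelin basic protein, differed by 4.51, Olig1 by 2.16, Mag by 1.29 and Cnp by 1.16, and 0 members passed over all probes or adjusted over the list alone. Mag was 8.65, 8.33 and 11.93 on the congenic arrays. Without congenic array 3 the differences of Mbp, Olig1, Mag and Cnp were 2.99, 1.11, 0.14 and 0.39, and without wild type array 1 that of Cnp was 0.50. The median of the list was 0.61 without congenic array 3 and 1.86 without congenic array 1, and without wild type array 1 it was 0.99, with 4 of 6 positive. The camera adjusted p of these markers in limma was 0.427 without wild type array 1 and 0.240 without congenic array 3, and 0.00225 with wild type and congenic array 1 both left out. The number of lists called was 2 without congenic array 1 or 3 or wild type array 2 or 3, and 3 without wild type array 1. The other 27 lists gave camera adjusted p-values of 0.0883 to 0.979 in limma.

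Without wild type array 1, camera called 3 lists. Dopamine, opioid and reward genes were lower, with 16 of 22 negative and a median of -0.36 (camera in limma, adjusted p = 0.0403; adjusted p = 0.873 with an estimated correlation). Slc6a3 passed adjusted over the list alone (limma adjusted p = 0.00103), 0 members passed over all probes, and the dopamine receptor Drd2 differed by -1.29, the aldehyde dehydrogenase Aldh1a1 by -0.85 and the opioid receptor Oprd1 by 1.12. Over all 6 arrays Oprd1 differed by 0.44, and by 0.13 and 0.06 without wild type array 2 or 3. Genes of GABA and glutamate signalling were higher, with 12 of 17 positive and a median of 0.34 (camera in limma, adjusted p = 0.0403; adjusted p = 0.873 with an estimated correlation). The receptor subunits Gria3, Gabra3, Gabra2 and Gabrb2 differed by 0.95, 1.54, 0.82 and 0.42, and 0 members passed over all probes or adjusted over the list alone. Over all 6 arrays the median of this list was 0.92 and Gabrb2 differed by 2.09, and a second, dimmer probe of it by -0.14 without wild type array 1. Gabra3 gave 1.25 over all 6 arrays, 0.75 without wild type array 2 and 1.89 without congenic array 1. Gabra2 gave 0.95 over all 6 arrays, 0.59 without congenic array 3 and 1.49 without congenic array 1. With chromosome 17 genes left out, the camera adjusted p in limma was 0.0895 for the first of these lists and 0.0651 for the other. Anterior pituitary markers were higher, with 8 of 9 positive and a median of 1.22 (camera in limma, adjusted p = 0.00781; adjusted p = 0.873 with an estimated correlation). Ghrhr, Lhb, Cga and Gh, a receptor and hormone genes of the pituitary, differed by 1.22, 0.83, 1.38 and 3.33, and 0 members passed over all probes or adjusted over the list alone. Gh, Prl and Pomc were high on congenic array 1: Gh was 17.46 there and at most 8.86 on the other 2 congenic arrays and wild type arrays 2 and 3, Prl 14.94 against 8.38 and Pomc 18.18 against 12.97. Ghrhr (8.33 to 8.88) and Lhb (10.99 to 11.49) were higher on each congenic array than on wild type arrays 2 and 3, where they were at most 7.75 and 10.60, and Ghrhr was 8.80 on wild type array 1. Cga did not separate so, as it was lower on congenic array 3 than on wild type arrays 2 and 3. The Ghrhr values all lay below the array median of 8.98, so they cannot be told from background. Over all 6 arrays the median of the list was 0.77, and Ghrhr and Cga both differed by 0.77. With congenic array 1 alone left out, the median was 0.25, and Cga and Gh differed by 0.14 and 0.51. With congenic array 1 also left out, the camera adjusted p of the pituitary markers in limma was 0.476.

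Whether the strain difference itself differed between tissues was tested on the 12 arrays, and limma called 0 probes, with 1198 at an unadjusted p under 0.05. The arrays were treated as independent, and a fit that linked the arrays of a strain with the same number also called 0. The labels leave it unclear whether both tissues came from the same mice and congenic line, so line and tissue are not separated here. H2-Ea had the smallest p among named genes, with a difference of 5.31 in muscle and 0.81 in hypothalamus (4.50 between them; limma adjusted p = 0.913). Next, with larger values in muscle, were Cyp4f14 (4.43), Efna2 (2.95), Pcdha4 (2.72) and Marcksl1 (2.88), and with smaller values in muscle Psapl1 (-3.50), Lmx1a (-2.37), Sec61a1 (-2.30), Cenpi (-2.17) and Atxn7 (-3.06), each with a limma adjusted p of 0.913. Without wild type hypothalamus array 1, limma called 0 probes, with 2224 at an unadjusted p under 0.05. The smallest adjusted p was then 0.0528, for H2-Ea, with 4.94. By the same rule, Pllp (2.24), Slc6a3 (3.41), Thbs4 (2.32) and Cnpy3 (2.16) had larger values in muscle, and Ddx1 (-3.43), Olfr298 (-3.94), Sec61a1 (-2.07), Tmed9 (-1.68) and Tubb2b (-2.001) smaller ones, each with a limma adjusted p of 0.468. Over all 12 arrays Slc6a3 gave 1.33, Pllp 0.55, Ddx1 -1.93, Tmed9 -0.59 and Tubb2b -1.04. With wild type hypothalamus array 2 or 3 left out in place of array 1, Slc6a3 gave 0.37 and 0.20 and Tubb2b -0.66 and -0.46. Ddx1 gave -0.70 without wild type hypothalamus array 2.

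The genes Rsph1 and Taf11 differed the same way in both tissues at an unadjusted limma p under 0.01, both on chromosome 17. Rsph1 was higher in congenic mice, where 0.0400 genes would be met by chance (Fisher's exact test, p = 0.0393), and Taf11 was lower, where 0.0224 would be (Fisher's exact test, p = 0.0222). Without wild type hypothalamus array 1 the shared genes were Dynlt1b and Rsph1 on the higher side (0.291 by chance; Fisher's exact test, p = 0.0343) and Pla2g7, Rnaset2b and Taf11 on the lower side (0.251 by chance; Fisher's exact test, p = 0.00197). All of these were on chromosome 17, and 0 genes on other chromosomes were shared. Elsewhere only 0.182 (higher) and 0.159 (lower) would be met by chance without that array, so the 0 says little. Probes without a gene name were not counted, and their chromosome is unknown. Of these, 858145 (-5.11 in muscle) differed in hypothalamus by -3.94 over all 6 arrays and by -3.08 without wild type array 1. Probe 366579 (-2.68 in muscle) gave 0.39 and -2.66 in the same order. Across genes, which are not independent replicates, the Pearson correlation of the strain differences in the tissues was 0.0554 on chromosome 17 and -0.0650 elsewhere, and 0.113 and -0.0737 without that array. Here too the congenic line may not be the same in both tissues. The number of shared genes was 1 without congenic hypothalamus array 1, 2 or 3 in turn.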

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

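The adjustment over the 6 probes called in muscle and the test of the share of higher genes were chosen after the results were seen.

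The strain effect on H2-Ea was larger in muscle than in hypothalamus by 4.50 (log2; 5.31 against 0.81), and that on Atp6v0e by 1.81 (1.80 against -0.01). Both were picked out by the interaction test of limma, with adjusted p-values of 0.000189 and 0.0337 over the 6 probes called in muscle. These probes were selected on the same muscle values, so this is not independent evidence, and over all probes the adjusted p was 0.913 for both. Without wild type hypothalamus array 1 the differences were 4.94 and 1.69, with adjusted p-values over the 6 probes of 9.60e-06 and 0.00984, and probe 858145 passed too (-2.03, adjusted p = 0.0463; over all arrays -1.17, adjusted p = 0.356). Whether both tissues came from the same congenic line is not clear from the labels, so a difference between lines is open and was not tested. Beyond leaving out each array in turn, single distant values within groups of 3 arrays were not tested for.

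The excess of strain differences on chromosome 17 may come from the transferred segment or from CAST sequence variants under the probes, which would lower the signal of a CAST transcript. Variants alone would make nearly all of these genes lower, but 67.9% (47.6% to 84.1%) of the 28 chromosome 17 genes in muscle were higher. This argues against variants as the only cause of the excess in muscle. That a variant did not raise the higher genes follows from the premise and was not tested by this share. In hypothalamus 1 of 4 was higher (0.631% to 80.6%), and without wild type array 1 11 of 28 (39.3%, 21.5% to 59.4%). These intervals leave open which direction prevailed, and variants stay open for the genes that were lower. For the 9 lower genes, Taf11 and Pla2g7 among them, the test had no material, since 0 of them had a second probe, so a variant under the probe and a lower transcript level cannot be told apart. For H2-Ea, B6 mice are known to lack transcription of this gene because of a deletion in its promoter. An intact CAST allele is thus a candidate explanation, although the allele was not measured here. H2-Aa, another class II gene, differed by -0.92 in muscle, which speaks neither for nor against this explanation.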

How the results depend on the processing

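The fit without wild type and congenic hypothalamus array 1 was chosen after the data were seen. All other alternatives were planned. Quantile normalization again and median centring moved nothing, since the arrays of a tissue already shared 1 distribution. In muscle the 6 calls became 2 with a floor at the 20th percentile, 2 without the trend, 1 in a fit of all 12 arrays, 0 with a plain equal-variance test and 2 to 8 with 1 array left out. They stayed at 6 to 9 with robust variances, a replicate block, a filter on dim probes or array weights. The 5 muscle lists became 0 with an estimated correlation, 0 with fry and 1 to 7 with 1 array left out. In hypothalamus the strain effect gave 0 calls in every alternative run. The 1 list called became 3 with a replicate block, 0 with an estimated correlation, 0 with fry, 3 without both arrays and 1 to 3 with 1 array left out. The odds ratio of chromosome 17 was 3.84 to 8.61 in muscle and 2.16 to 6.07 in hypothalamus with 1 array left out. The 2 shared genes became 0 at an adjusted p under 0.05, 9 at an unadjusted p under 0.05, 4 without both arrays and 1 to 5 with 1 array left out. The interaction gave 0 calls in every alternative run. Directions reversed for Pla2g7 in hypothalamus (0.68), at -1.71 with array weights, -1.73 without wild type array 1 and -1.76 without both arrays, with a range of -1.73 to 2.03 over the arrays left out. Probe 366579 in hypothalamus (0.39) gave -2.58, -2.66 and -2.55 in the same order, with a range of -2.66 to 1.93. Stk32c in hypothalamus was -0.27 and -0.11 without wild type arrays 2 and 3, with a highest value of 2.35. The interaction value of Pllp was -0.36 and -0.22 without the same arrays, with a highest value of 2.24, and that of Tmed9 was 0.023 without wild type array 2 and lowest at -1.68. Fewer arrays are part of the leave-out results. For the other alternatives the cause was not tested. The replicate numbers were not taken to pair samples, since no label says that they do. Correlations across probes between congenic and wild type arrays of the same number, each relative to its group mean, were 0.0695, 0.0147 and 0.0634 in muscle and 0.0343, -0.129 and 0.138 in hypothalamus. In muscle, and between congenic muscle and congenic hypothalamus, every array correlated best with that of its own number. In hypothalamus, and between the wild type tissues, only number 1 did. Both of these comparisons use the mean of the wild type hypothalamus arrays, which holds array 1 that stood apart. They therefore say little about the numbers. A batch or mouse marked by the numbers is thus not excluded. Signal over background is unknown, which limits every low value.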

Other observations

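The tests of muscle RNA and of degraded RNA on wild type hypothalamus array 1 and of the strain as a source of pituitary genes were chosen after the results were seen. The pituitary levels of Gh, Prl and Pomc had also been seen before the test on other pituitary genes was chosen.

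On wild type hypothalamus array 1 Hcrt, the orexin precursor, was 9.06 and 16.30 to 19.10 on the other hypothalamus arrays, and Pomc was 8.68 against 11.97 to 18.18, while Oxt, Avp and Eef1a1 were 18.69, 16.87 and 20.14. A loss on part of the array's probes may account for this: 24 of 56 bright probes of ribosomal protein genes were lost (42.9%, interval 29.7% to 56.8%), as were 33.3% of the other bright probes. Other cells in the sample might lose the probes of a gene together, but the loss at both bright probes of a gene correlated at 0.188 (-0.0760 to 0.428, 57 genes). How closely such probes of a gene agree on the other arrays was not measured, so this correlation does not decide. Every cell uses ribosomal protein genes, so the loss of 24 of 56 of their probes argues against other cells as the only cause. A part played by other cells stays open. Degraded RNA stays open: loss would depend on a probe's distance from the 3' end, which was known for 0 bright probes. A muscle sample is argued against by a muscle marker median that was -11.33 relative to the muscle arrays. Other biological differences of that mouse were not tested.

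The pituitary hormone genes Gh, Prl and Pomc were high on congenic hypothalamus array 1. Pituitary tissue in the sample may be the source. Of 7 pituitary genes outside the fixed list only Lhx3, Lhx4, Foxl2 and Neurod4 were measured. Their median excess was 0.574, with an upper bound of 1.28 for the mean. On this array Lhx4, Foxl2 and Neurod4 were 8.80, 8.71 and 7.90, below its median of 8.98. Such low values cannot be told from background, so this test does not decide and pituitary tissue stays open. For Gh, Prl and Pomc the congenic strain as the source is argued against, since the larger of their medians on congenic arrays 2 and 3 was -0.0791 relative to wild type arrays 2 and 3.

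Other splits of the 6 arrays of a tissue into groups of 3 number 10 with the real one, too few for a share under 0.05. In muscle the real split gave 6 calls and the highest other 1, so 1 of 10 splits was as large. For chromosome 17 the odds ratio was 7.12 against 2.18 (1 of 10), and for lists the counts were 5 and 9 (2 of 10). The split with 9 lists set congenic arrays 1 and 2 and wild type array 1 against the rest. In hypothalamus the figures were 0 calls and 0 (10 of 10), which every split must reach, an odds ratio of 6.21 and 5.04 (1 of 10), and 1 list and 4 (7 of 10). For the interaction, 100 of 100 drawn splits gave at least the 0 calls found, the highest other being 3. Every split reaches a count of 0, so this says nothing about chance. For the genes shared between tissues, 1 of 100 drawn splits gave as many as 2, which was the real one, and the highest other gave 1. The draws regrouped each tissue on its own. If each mouse gave both tissues, the groups would move together and only 10 splits would exist. That is too few, so a random split as the source is not decided.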
